A study of Homo sapiens with 24 samples.

How the data were processed

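MicroRNAs (miRNAs) of stored red blood cells were counted with the NanoString nCounter human miRNA v2 panel, which counts coloured barcodes on hybridised probes without amplification. Per the labels' protocols, whole blood was collected in an additive solution, depleted of leukocytes, packed and kept refrigerated, serial aliquots of each unit were taken under sterile conditions, and small RNA was isolated with a column kit after non-human miRNAs had been added. The labels gave 24 samples from 3 blood units, each sampled at 8 storage days from day 1 to day 42 (the others being days 3, 7, 10, 14, 28 and 36). The group of a sample was its storage day (n = 3) and the replicate number was its unit.

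The raw table deposited by the authors holds, per the file headers, 800 endogenous miRNA probes, 6 positive controls, 6 negative controls, 5 mRNA controls and 5 non-human spike-ins. Its probe values are whole barcode counts. They were entered as estimated counts (the expected count class) of the deposited table because the same columns also hold instrument readings that are not whole, and only the probe rows were used, so no rounding was needed. A further 3 columns of that table matched no sample label and were not used. The deposited normalized table and the deposited value table of the series hold a rounded score per probe. Of 19320 values in the normalized table outside the spike-ins, 19320 lay within 1 count or 0.1% of the raw count times 1 factor per sample. That factor followed the geometric mean of the positive controls with a largest difference of 0.01% and ran from 0.40 to 2.87, and 120 of 120 spike-in values were the raw counts. The deposited scores were therefore scaled to positive controls, whereas the labels' protocols name the added non-human miRNAs as the reference. In the series value table, 19440 of 19440 values were those of the normalized table. The files name no genome build, so no coordinates are given, and a gene table of the assembly GRCh38.p14 served only to look up gene neighbours.

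The plan made before the data were examined (the groups, tests, lists, naming rule and the first set of alternatives) scaled counts to spike-ins above background in every sample and named the trimmed mean of M-values (TMM) as the main scaling if fewer than 2 qualified. Background was the mean plus 2 SD of a sample's negative controls. Only 1 spike-in, cel-miR-254, qualified, so TMM was used. A miRNA was tested if its count exceeded background in at least 6 of the 24 samples. This left 132 miRNAs, which held 99.0% of the endogenous counts, and 668 were not tested. Normalized counts are counts per 1000000 of the TMM-scaled endogenous total. They need not sum to 1000000 in a sample and are not shares of its counts.

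Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the blood unit as a block and Benjamini-Hochberg adjustment at 0.05. The storage trend used day as a number and is given as the fitted log2 change over the 41 days from day 1 to day 42. Day as a factor gave day 42 against day 1, each later day against day 1, and any change over the 7 later days. Lists of miRNAs with at least 3 tested members were tested on the trend with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. The lists were erythroid, tRNA-overlapping, snoRNA- or snRNA-overlapping, let-7, miR-17 family clusters, platelet, lymphocyte, myeloid and pan-leukocyte, liver, muscle, and miRNAs of earlier storage work, with the mRNA controls given as values. The slope on day of the total endogenous count over cel-miR-254 was tested with a two-sided permutation test of 100000 resamples, permuting days within units, and a like test of any difference between days was added after the values were seen. With the unit as a block, the p-values of the day comparisons measure the spread of samples within and across 3 units after unit means are taken out, and permutation p-values of correlations permute samples within units.

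The unit was a block because the labels' protocols describe serial aliquots of 1 unit. Over 84 pairs of samples from the same unit, deviations from the day means had a median correlation of 0.60, against -0.30 between units. No 2 libraries were duplicates: the smallest chi-square per degree of freedom among 276 pairs was 22.7. Each unit ran in its own cartridge, so unit and cartridge cannot be told apart, and in each unit the days ran in ascending order of lane, so lane and day cannot be told apart either.

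Named miRNAs followed a fixed rule. From the trend it took up to 12 rising and 12 falling miRNAs past the threshold with the same sign in each of the 3 units, or, where none passed, the 3 with the smallest p in that direction. It added the 10 most abundant miRNAs, the 2 to 4 most abundant tested members of each list, and miR-720, miR-451a, miR-16-5p and miR-486 as single names. miR-144-3p at day 3, miR-32-5p, miR-152 at day 3, miR-33a-5p, miR-520f and miR-941 were named after their values were seen.

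The tests were tried on 20 simulated data sets of 132 miRNAs with the real means, depths and spread about the trend, 30 of them changed. For the storage trend, 85.5% of miRNAs changed 2-fold, 98.0% of those changed 4-fold and 100.0% of those changed 8-fold were recovered. For day 42 against day 1 the shares were 62.5%, 93.5% and 99.0%. For any change over storage days they were 56.0%, 94.0% and 99.5%. In 20 data sets with no change, a miRNA was called in 1 for the trend, 2 for day 42 against day 1 and 0 for any change. The simulated changes were steady over days, and counts were drawn independently for each miRNA. Deviations that many miRNAs of a library share were therefore absent, so these rates need not hold for the real libraries. With the real days permuted within units, 5 of 100 arrangements, the real one included, gave 5 or more any-change calls. The alternatives set in advance were DESeq2 size factors, the 100 most abundant miRNAs or positive controls as scaling, limma on log2 of the authors' score with a pseudocount of 1 or 10, no filter, a filter of 12 samples, no block, leaving out each unit, log2 of day, and leaving out day 1 or day 42. Spike-in scalings, DESeq2 1.42.0 with the TMM factors, leaving out single libraries or day 3, and binding density (the crowding of barcodes in a lane) as covariate were added after the data were seen. The 3 spike-ins used together were cel-miR-254, osa-miR414 and osa-miR442. Of these, osa-miR414 exceeded background in 13 and osa-miR442 in 19 of 24 samples. A DESeq2 test with spike-in factors was also foreseen and was not run, since spike-in factors were not the main scaling. Figures were drawn with matplotlib 3.10.9.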

Results

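miRNA levels were measured in leukocyte-depleted packed red blood cells over the permitted storage time, to follow the miRNA profile of the cells outside the body. Aliquots of 3 units at 8 storage days gave 24 samples, with 3 samples per day. Total endogenous counts ran from 327411 in the unit 2 day 14 sample to 898860, with a median of 829069 and a next lowest value of 555513. Binding density ran from 0.83 in the unit 2 day 14 sample to 3.62 in the unit 1 day 3 sample. The positive controls fell as binding density rose (Pearson r -0.94). Of 800 miRNA probes, 59 exceeded background in all 24 samples and 609 in none, and 132 were tested. The mRNA controls ACTB, B2M, GAPDH, RPL19 and RPLP0 exceeded background in 0 of 120 values, with a highest count of 61.

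The profile was dominated by miR-451a, an erythroid miRNA needed for red cell maturation. It made up 53.5% ± 3.3 (SD, n = 3) of endogenous counts at day 1 and 56.0% ± 5.9 (SD, n = 3) at day 42. miR-16-5p followed, at 140900 ± 23300 normalized counts at day 1 and 147600 ± 49210 at day 42 (SD, n = 3). miR-144-3p, whose gene neighbours that of miR-451a, stood at 39000 ± 6335 normalized counts at day 1 (SD, n = 3). The other miRNAs among the 10 most abundant were let-7g-5p, miR-15b-5p, miR-15a-5p, miR-25-3p, miR-142-3p, let-7a-5p and miR-19b-3p. Their day 1 means ran from 10300 normalized counts for miR-19b-3p to 31150 for let-7g-5p. None of the 10 passed the trend test or the test of day 42 against day 1. The fitted change over storage was 0.01 ± 0.16 on the log2 scale (SE) for miR-451a and 0.04 ± 0.11 for miR-16-5p. The panel table used here held miR-486-3p as its miR-486 probe, with a fitted log2 change of -0.01 ± 0.44 (SE).

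The first comparison asked which miRNAs changed steadily with storage day. None of the 132 miRNAs passed the edgeR quasi-likelihood test of the trend, and the smallest adjusted p was 0.23. At an unadjusted p under 0.05 there were 12, of which 6 had a positive and 6 a negative slope, where 6.6 were to be expected by chance. The smallest p-values with a positive slope belonged to miR-454-3p (log2 change 0.48 ± 0.15), miR-720 (1.57 ± 0.51) and miR-20a-5p+miR-20b-5p (0.32 ± 0.11), the last a probe shared by 2 miRNAs. Those with a negative slope belonged to miR-152 (-1.01 ± 0.35), miR-30b-5p (-0.47 ± 0.19) and miR-483-3p (-0.42 ± 0.18). Each of these 6 slopes had its sign in 3 of 3 units, and errors are SE over 24 samples. DESeq2 with the TMM factors also called 0. miR-720 alone passed with log2 of day as the time scale (log2 change 2.69 ± 0.42, adjusted p = 1.53e-04 by edgeR), with positive controls as scaling (adjusted p = 0.012 by edgeR) and with limma on the authors' score (adjusted p = 0.0032 with a pseudocount of 1).

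No list of miRNAs passed the trend test as a group. Among 19 tested erythroid miRNAs, 9 slopes were positive and 10 negative, and 0 passed singly. The examples miR-15b-5p and miR-144-3p had fitted log2 changes of -0.13 ± 0.15 and -1.20 ± 0.57 (SE). That of miR-144-3p was 0.00 ± 0.47 without the day 3 libraries and -0.51 ± 0.50 with binding density, the crowding of barcodes in a lane, as covariate. The miR-17 family clusters, which drive proliferation in blood precursors, came nearest to a shift. Of 11 tested members, 7 slopes were positive and 4 negative, with 0 past the threshold, a camera p of 0.011 and an adjusted p of 0.076 over 7 lists. With an estimated correlation the adjusted p was 0.32. Its members included miR-25-3p (log2 change 0.35 ± 0.17), miR-93-5p (0.32 ± 0.13) and miR-92a-3p (-0.37 ± 0.26). The 9 let-7 members had a median log2 change of 0.04, with let-7b-5p at 0.00 ± 0.22 and let-7i-5p at 0.13 ± 0.11, and a camera adjusted p of 0.78.

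Markers of other blood cells also gave 0 trend calls. Among the platelet, myeloid and lymphocyte members named here, day 1 means ran from 190.7 ± 48.6 normalized counts for miR-29c-3p to 15850 ± 848 for miR-142-3p (SD, n = 3), which was among the 10 most abundant miRNAs. The platelet list had 5 tested members, 3 with positive slopes, and its examples included miR-126-3p (0.12 ± 0.10) and miR-21-5p (-0.30 ± 0.26). The myeloid and pan-leukocyte list had 3 tested members, including miR-142-3p (-0.31 ± 0.30) and miR-223-3p (0.06 ± 0.12), the latter a granulocyte miRNA also held by the platelet list. The 4 tested lymphocyte members included miR-29b-3p (-0.36 ± 0.30), miR-29c-3p (0.13 ± 0.26), miR-181a-5p (0.33 ± 0.18) and miR-342-3p (-0.19 ± 0.15). The camera adjusted p was 0.78 for the platelet list, 0.78 for the myeloid and pan-leukocyte list, 0.87 for the lymphocyte list and 0.84 for the erythroid list. Of the liver list miR-194-5p (0.16 ± 0.10) and miR-192-5p (-0.18 ± 0.19) were tested, of the snoRNA- or snRNA-overlapping list miR-664-3p (-0.26 ± 0.15), and of the miRNAs of earlier storage work miR-96-5p (-0.35 ± 0.24). No muscle miRNA was above the filter. Adjusted over the list alone, 1 of the 3 tested tRNA-overlapping probes passed the trend test and 0 members of every other list. The tRNA-overlapping list had a median log2 change of -0.42, a mean of 0.22 and a camera adjusted p of 0.78 in the upward direction. The erythroid and lymphocyte lists also had medians (-0.01 and -0.03) and means (-0.07 and -0.02) below 0 with an upward camera direction.

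Day 42, the end of permitted storage, was compared with day 1. miR-720, a probe that the lists fixed in advance place among those overlapping transfer RNAs, was higher at day 42 by 5.27-fold. Probe sequences were not at hand to check that placement. Its normalized count was 131.0 ± 45.4 at day 1 and 736.2 ± 422 at day 42 (SD, n = 3), a log2 change of 2.40 ± 0.36 (SE) with an edgeR adjusted p of 3.29e-04. It was the 1 miRNA of 132 past the threshold, and 12 had an unadjusted p under 0.05. The other tested tRNA-overlapping probes, miR-4454 and miR-1260a, had log2 changes of -0.09 ± 0.34 and -0.24 ± 0.40 (SE) and did not pass. Without unit 1 the log2 change of miR-720 was 2.09 ± 0.53 and it no longer passed (edgeR adjusted p = 0.24). Without the unit 2 day 10 library, which enters this comparison through the spread, 7 miRNAs passed, 2 higher and 5 lower.

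**Figure D1:**
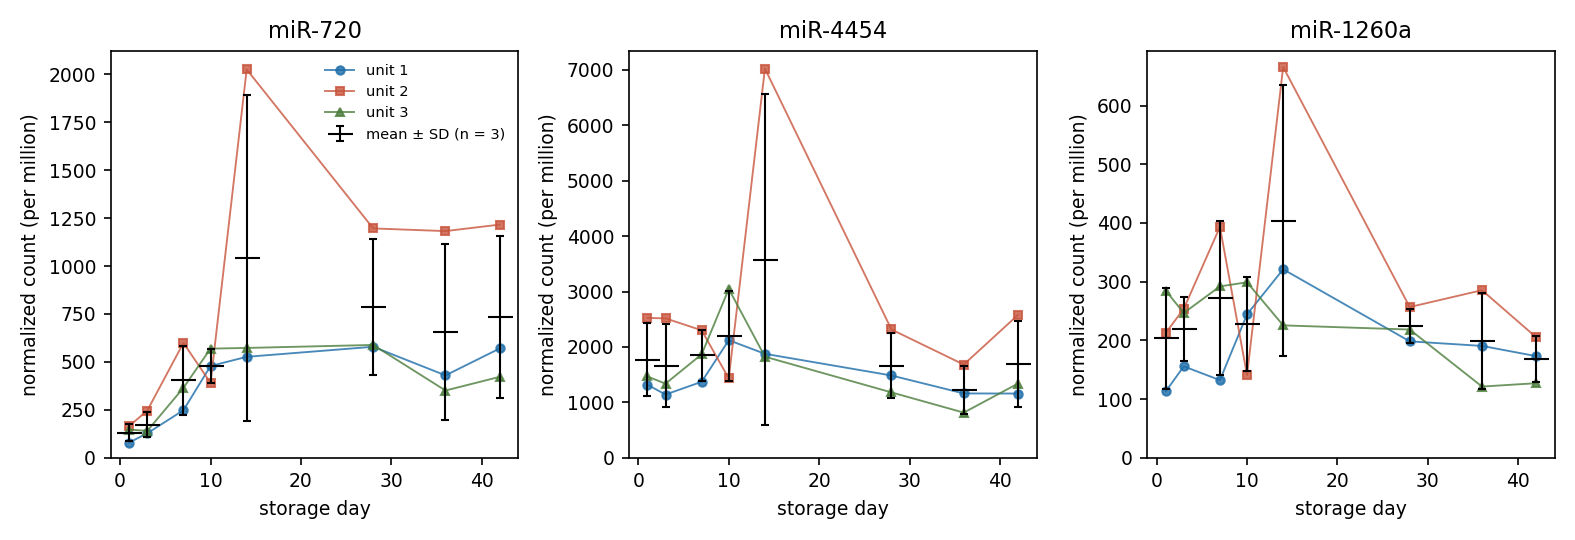
Normalized counts, per 1000000 of the TMM-scaled endogenous total (vertical axis, linear, from 0) of the 3 tested tRNA-overlapping probes against storage day. Coloured lines are the 3 units and black bars the mean ± SD of 3 samples. miR-720 goes from a mean of 131.0 at day 1 to 736.2 at day 42, while miR-4454 is at 1770 and 1693 and miR-1260a at 203.5 and 168.5.

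Each later day was also set against day 1, with the same 3 day 1 samples in all 7 comparisons. miR-720 was higher at days 7, 10, 14, 28, 36 and 42. Its fold over day 1 was 1.28 at day 3, which did not pass, then 2.96 at day 7, 4.06 at day 10, 6.88 at day 14, 5.78 at day 28 and 4.51 at day 36, the last 5 with edgeR adjusted p-values from 5.04e-05 to 0.037. miR-33a-5p, a miRNA of the cholesterol-regulating SREBF2 gene, was higher at day 3 (7.57-fold), day 10 (3.51-fold) and day 28 (2.91-fold). With the fixed filter, TMM and no covariate, edgeR on all 24 samples called no other miRNA at any day, and unadjusted p-values under 0.05 numbered 32 at day 3, 7 at day 7, 4 at day 10, 22 at day 14, 4 at day 28, 1 at day 36 and 12 at day 42. These 2 became 16 with binding density as covariate, 97 with cel-miR-254 and 132 with 3 spike-ins as scaling. The 3 spike-ins include osa-miR442, whose mean raw count was 63.3 at day 1 and 287.0 at day 3. In all, 62 miRNAs were called at 1 or more later days without the unit 2 day 10 library, with 33 of them called at day 3 (10 higher, 23 lower), and 10 without the unit 2 day 14 library. The raw count of miR-33a-5p was nearly that of the rice spike-in osa-miR442 in every sample, with ratios from 0.71 to 1.17. Over 24 samples the log2 counts had a Pearson r of 0.98 and a Spearman rho of 0.98, each with a permutation p of 1.00e-05, the smallest these permutations can give. Within units r was 0.97, 0.99 and 0.98, and without the 2 samples farthest from the median of osa-miR442 it was 0.98. Among 660 relations of 5 spike-ins with 132 miRNAs its adjusted permutation p was 0.0033.

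**Figure D2:**
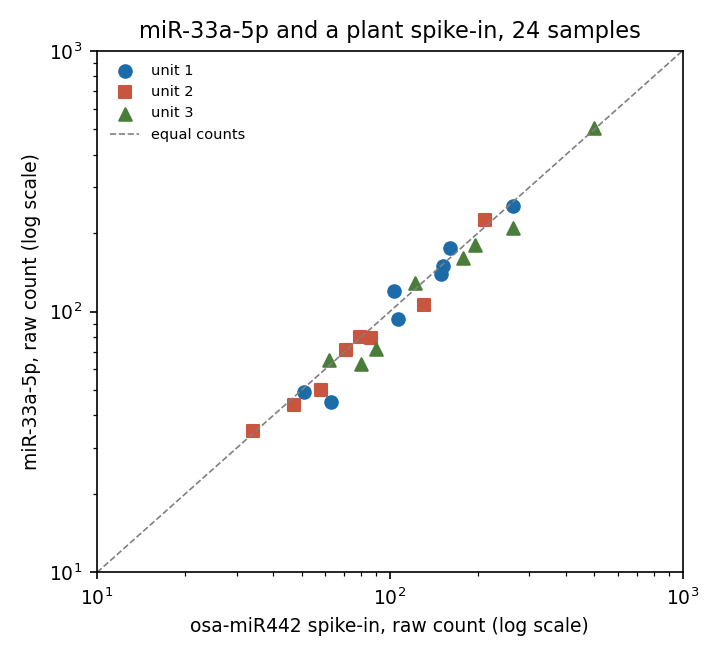
Raw count of miR-33a-5p against the raw count of the spike-in osa-miR442 in 24 samples, both axes logarithmic. Symbols mark the 3 units and the dashed line marks equal counts. The points follow that line, with ratios between 0.71 and 1.17.

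The test for any change over storage days called 5 of 132 miRNAs, against 35 with an unadjusted p under 0.05. They were miR-33a-5p (adjusted p = 7.68e-05), miR-720 (1.50e-04), miR-144-3p (0.016), miR-32-5p (0.018) and miR-152 (0.028), all by edgeR. The calls of miR-144-3p, miR-32-5p and miR-152 ended with positive controls as scaling (adjusted p = 0.22, 0.25 and 0.22 by edgeR) and with limma on the authors' score (0.22 each with a pseudocount of 1). Without unit 1 miR-144-3p and miR-32-5p (0.32 each by edgeR) and miR-720 (0.19) were no longer called and miR-152 was not tested, and without unit 3 miR-144-3p and miR-32-5p (0.24 each by edgeR) and miR-152 (0.32) were no longer called. With osa-miR442 as covariate only miR-720 of the 5 was still called, with edgeR adjusted p-values of 0.69 for miR-33a-5p and 0.18 for each of the other 3. In contrast, 86 miRNAs were called with cel-miR-254 and 128 with 3 spike-ins as scaling. Of those spike-ins, which include osa-miR442, only cel-miR-254 exceeded background in all 24 samples. The miRNAs miR-144-3p, miR-32-5p and miR-152 had their highest mean at day 3. miR-144-3p had 146700 ± 36690 normalized counts at day 3 against 39000 ± 6335 at day 1, miR-32-5p 2007 ± 72.8 against 543.0 ± 55.0, and miR-152 153.3 ± 55.8 against 74.2 ± 20.2 (SD, n = 3). Set against day 1 alone, none of these 3 passed at day 3, with adjusted p-values of 0.087, 0.087 and 0.17 by edgeR. miR-451a stood at 703500 ± 177100 normalized counts at day 3 and 505700 ± 67800 at day 1 and was not called (any-change adjusted p = 0.41 by edgeR). Its share of endogenous counts was 55.6% ± 4.3 at day 3 and 53.5% ± 3.3 at day 1 (SD, n = 3). Adjusted over the list alone, the any-change test called 2 tRNA-overlapping probes and 1 member each of the erythroid, miR-17 family, lymphocyte, and myeloid and pan-leukocyte lists. The 3 miRNAs high at day 3 were also high in the unit 2 day 10 library, and without that library 58 miRNAs passed the any-change test. Without the day 3 libraries 2 miRNAs passed, miR-33a-5p and miR-720.

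**Figure D3:**
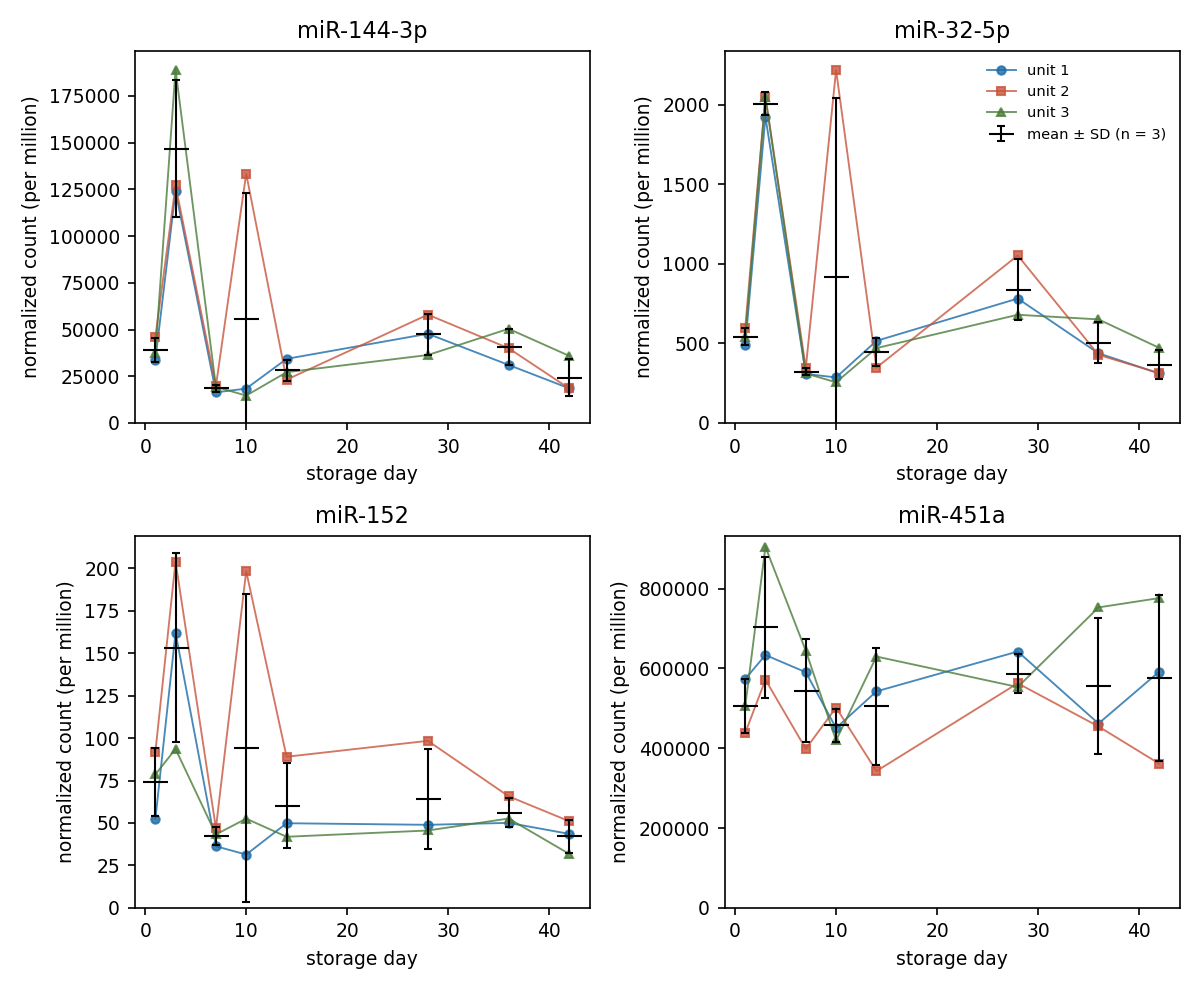
Normalized counts, per 1000000 of the TMM-scaled endogenous total (vertical axes, linear, from 0) of miR-144-3p, miR-32-5p, miR-152 and miR-451a against storage day. Coloured lines are the 3 units and black bars the mean ± SD of 3 samples. The first 3 have their highest means at day 3 and are also high in the unit 2 sample at day 10, with day 3 means of 146700, 2007 and 153.3.

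The summed endogenous miRNA signal, set against the spike-in cel-miR-254, had no slope over storage beyond its spread. This ratio differed between days, but no such difference passed with positive controls as the reference or for the raw total. On the log2 scale the ratio was 11.04 ± 0.06 at day 1, 10.48 ± 0.22 at day 10, 10.20 ± 0.46 at day 28 and 11.21 ± 0.39 at day 42 (SD, n = 3). It was below day 1 in 3 of 3 units at days 7, 10 and 28, by a mean log2 difference of -0.24 ± 0.24, -0.55 ± 0.21 and -0.84 ± 0.42 (SD, n = 3). The fitted change over 41 days was 0.07, with a two-sided permutation p of 0.78. A permutation test of any difference between days, chosen after the values were seen, gave p = 0.0045 with cel-miR-254, 0.16 with positive controls and 0.87 for the raw total. Raw totals at day 28 were 835626, 879163 and 765522 in units 1, 2 and 3, against 691538, 877398 and 789467 at day 1. The ratio cannot separate a loss of miRNA from a higher count of cel-miR-254, which ran from 161 to 847. With positive controls as the reference the change over 41 days was -0.01 and its permutation p was 0.98.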

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

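Settings that change the scaling to spike-ins, leave out single libraries or day 3, add binding density, or use the DESeq2 test were chosen after the data were seen, as were all settings for each later day. The trend count of 0 became 1, miR-720 each time, with positive controls, limma on the authors' score at both pseudocounts, log2 of day and 3 spike-ins, and stayed at 0 otherwise, with DESeq2 size factors (set in advance) and without each unit included. The 1 call at day 42 became 2 without the filter, 7 without the unit 2 day 10 library and 0 to 1 without each unit, and was miR-720 under every other setting. The 5 any-change calls became 2 with positive controls, 2 with limma at either pseudocount, 2 without the day 3 libraries, 8 with binding density as covariate, 11 without the filter, 30 with DESeq2, 58 without the unit 2 day 10 library, 86 with cel-miR-254 alone, 128 with 3 spike-ins and 1 to 48 without each unit. The 2 miRNAs called at any later day became 10 without the unit 2 day 14 library, 16 with binding density, 62 without the unit 2 day 10 library, 97 with cel-miR-254 alone, 132 with 3 spike-ins and 2 to 36 without each unit. The 48 and the 36 came without unit 2. The cause of these shifts was not tested. Without each unit, 0 to 1 lists passed, the 1 being the miR-17 family clusters without unit 2 (adjusted p = 0.033). The change in total signal of 0.07 was -0.01 with positive controls and -0.02 to 0.18 without each unit, and its slope passed no test.

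The fit with no replicate block called 0 miRNAs for the trend, 1 at day 42 (miR-720, adjusted p = 0.049), 4 for any change and 0 lists, and ended 1 call, that of miR-152. For 39 trend or day 42 results on single miRNAs there were 805 comparisons with an alternative: 799 stayed on their side of the threshold, 5 passed it (all the trend of miR-720), 1 no longer did (miR-720 at day 42 without unit 1), and 74 values changed sign with neither value past the threshold. The any-change calls of the 5 miRNAs ended in 18 of 86 comparisons: 6 of 18 for miR-144-3p, 6 of 18 for miR-32-5p, 5 of 14 for miR-152, 1 of 18 for miR-720 and 0 of 18 for miR-33a-5p, the fit with osa-miR442 as covariate not included. The median day 42 change of all tested miRNAs was -0.03 with TMM, -0.59 with positive controls, 0.10 with cel-miR-254 and -0.46 with 3 spike-ins, and that of miR-720 lay between 1.83 and 2.53 under these 4 scalings. At this depth and with 3 units, a 2-fold change was recovered less often than a larger one in simulation, so small changes can have been missed.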

Other observations

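Of the tests below, the sample splits, the permutations of days within units, the correlation of miR-33a-5p with osa-miR442 after taking out unit and day, and the fit with osa-miR442 as covariate were set before their results were seen, and the others afterwards. The fitted fold at day 3 over day 1 was 3.82 for miR-144-3p and 1.37 for miR-451a, which are made from neighbouring genes. Neither passed at day 3 (edgeR adjusted p = 0.087 and 0.20), and the difference between them was not tested. Without the unit 2 day 10 library, 33 miRNAs differed between day 3 and day 1 (10 higher, 23 lower), 32 between day 10 and day 1 and 7 between day 42 and day 1, by edgeR. Between the units, which coincide with cartridges, 92 of 132 miRNAs differed at an adjusted p under 0.05.

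miR-720 was higher at 6 of the 7 later days. A fall of the other miRNAs as the whole of this rise is argued against by the positive-control and spike-in scalings. Under these the day 42 log2 change of miR-720 was 1.83 with positive controls, 2.53 with cel-miR-254 alone and 1.99 with 3 spike-ins. The median of all tested miRNAs changed by -0.59, 0.10 and -0.46, so such a fall as part of the rise stays open. Positive controls fell with binding density (Pearson r -0.94), and only cel-miR-254 exceeded background in all 24 samples. The raw counts changed by a median of -0.05 in the other 131 miRNAs and by 2.38 in miR-720. This contrast decides nothing on a lane-wide effect, since miR-720 was picked as the 1 call after TMM, which takes out a shift shared by a lane. A rise shared by all tested tRNA-overlapping probes is argued against at day 42, where the higher of miR-4454 and miR-1260a changed by -0.09, but stays open at day 14, where they changed by 0.87 ± 0.35 and 0.95 ± 0.40 (SE; adjusted p 0.18 and 0.20 by edgeR; 0.30 ± 0.33 and 0.55 ± 0.43 without the unit 2 day 14 library). No test here separates a change in this RNA during storage from an effect of lane on this probe alone, since lane and day coincide. At day 42, 1 of the 10 splits of the 6 samples gave as many calls (1 real, 0 in the highest other), and 10 splits are too few for a share under 0.05.

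On the mean of their log2 levels, miR-144-3p, miR-32-5p and miR-152 were high at day 3 in 3 of 3 units. The mean rise was 1.93 over the unit's median of the other days. miR-152 was not tested with the filter of 12 samples, since it exceeded background in fewer. At day 3 its raw count was 76, 160 and 52 in units 1, 2 and 3, against backgrounds of 34.34, 71.08 and 52.44. Lane crowding was not settled by the fit with binding density as covariate. In that fit 3 of these 3 miRNAs kept an any-change adjusted p under 0.05 by edgeR. That test covers all later days, so it cannot show whether the day 3 rise kept its size. At day 3 binding density was 3.62 in unit 1, the highest of that unit. It was 2.22 and 2.23 in units 2 and 3, neither the highest of its unit. The unit 2 day 10 library, at 3.29, had the highest of unit 2. Lane crowding thus stays open. With osa-miR442, which was also high at day 3, as covariate, each of the 3 had an any-change adjusted p of 0.18 by edgeR (unadjusted 0.029, 0.038 and 0.0046). The day 3 log2 change went from 1.93 ± 0.54 to 1.86 ± 1.14, from 1.90 ± 0.51 to 2.49 ± 1.09 and from 1.02 ± 0.35 to 2.11 ± 0.77 (SE). The errors thus grew for all 3, and for miR-152 the estimate grew as well. Why the calls ended was not tested. The unit 2 day 10 library lay 2.39 above the next day 10 library on the log2 scale. That library was noticed in these same values, so the gap is no test of its cause. With a single library per unit and day, an effect of storage day in unit 2 stays open. Handling or a lane shared by the day 3 aliquots, which ran in the same lane number in 3 of 3 units, cannot be told apart from day 3 itself, and differences in RNA isolation or probe ligation, and a biological change at day 3, were not tested and stay open.

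miR-33a-5p may not be measured by its count, since signal of the spike-in osa-miR442 is a candidate source of it. The log2 counts had an r of 0.98, while the next tested miRNA reached 0.47 with this spike-in and the next spike-in 0.51 with miR-33a-5p. That both followed storage day on their own is argued against by an r of 0.95 after unit and day means were taken out. With osa-miR442 as covariate the any-change adjusted p of miR-33a-5p was 0.69 by edgeR, against 7.68e-05 without it, which leaves open a change of its own. miR-720 kept an adjusted p of 8.81e-04 in that fit.

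The days permuted within each unit gave 5 or more any-change calls in 5 of 100 arrangements, the real one included, with 22 in the highest other, so chance is not excluded for the count of 5. For the trend the real count was 0, which 100 of 100 arrangements necessarily reach (highest other 1), so the permutations decide nothing. For the 7 later days, with 10 splits each, too few for a share under 0.05, 1 split gave as many calls as the real one at days 3, 7, 14, 28, 36 and 42 (real counts of 1, 1, 1, 2, 1 and 1, highest other 0), and 4 did at day 10, where the real count was 2 and the highest other 36. Among the 4 splits that keep 1 sample of each unit on each side, 2 gave as many calls at day 10, with 8 in the highest other, and 1 did at each other day. The samples of the day 10 splits include the unit 2 day 10 library, and the cause of these higher counts was not tested.

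The spike-in ath-miR159a, above background in only 4 of 24 samples (median count 26), so that most of its values lie at background level, followed miR-520f (Pearson r 0.92, permutation p 3.00e-05; Spearman rho 0.91, permutation p 1.00e-04; r within units 0.56, 0.82 and 0.92; r 0.88 without the 2 farthest samples; adjusted p 0.0066 among 660 relations) and miR-941 (r 0.86 and rho 0.87, permutation p 1.00e-05 each; r within units 0.93, 0.79 and 0.88; r 0.82 without the 2 farthest samples; adjusted p 0.0033). The geometric mean of the positive controls fell with binding density over 24 samples (r -0.94 and rho -0.88, permutation p 1.00e-05 each, the smallest the permutations can give; r within units -0.97, -0.98 and -0.82; r -0.91 without the 2 farthest samples).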
